A study of Mus musculus with 24 samples.

How the data were processed

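Whole hearts of WT and DKO mice were collected at 24 weeks of age, per the labels' protocols, with 3 hearts for each combination of genotype, captopril or saline, and preconditioning or sham procedure. RNA was extracted with TRIzol, cleaned on a spin column, treated with DNase and checked by absorbance, and libraries were made with a stranded total RNA kit. The deposited counts are whole numbers of reads per gene symbol, 1 file per library, that the authors made by alignment and counting. Per the submitters' processing notes, TopHat, HTSeq and DESeq were used with the mm10 build, and their versions, parameters, annotation and roles are not given in the sources used here, nor is the strand setting of the counting. Reads of genes that overlap or lie antisense to each other could therefore not be told apart, and such genes, near-identical copies and pseudogenes are uncertain. RNA quality was assessed by absorbance only, so integrity values are not known here.

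Each file held 38931 lines, of which 5 were summary lines of the counting program and stayed out of library sizes and tests. Reads that fitted several genes made up 2.10% to 3.22% of counted and ambiguous reads, and reads aligned to several places 21.9% to 26.7% of all lines. The other 38926 lines were genes. Gene lengths, GC content, coordinates and biotypes came from the GENCODE M21 annotation of the same build (GRCm38), using the longest coding transcript per symbol, and 13393 of the 13494 tested genes (99.3%) had a match. RPL24 and Erdr1 had none.

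Groups and replicate numbers were taken from the labels. The 13 main comparisons, tests, gene lists, alternatives and the rule for the genes named in the text were fixed before the data were examined. Counts of all 24 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM normalization (factors 0.721 to 1.33), filterByExpr by group, 1 coefficient for each of the 8 groups and no block. Quasi-likelihood F tests gave 13 comparisons, with Benjamini-Hochberg adjustment over the 13494 genes at 0.05 and no minimum fold. Beyond these 13, the same fit and adjustment gave the genotype difference under each treatment and the captopril difference under HPC in each genotype. For each gene all 24 libraries share 1 estimate of the spread, because 3 hearts per group give few degrees of freedom (common dispersion over all genes 0.0635). The spread was not equal between the genotypes. The SD of the replicate axis score, defined below, was 44.9 to 48.0 in the WT groups and 10.9 to 28.5 in the DKO groups. A pooled spread can therefore be too small for comparisons within WT and too large for those within DKO. All adjusted p-values of single genes are from these tests, which are two-sided, and SE is the standard error of the log2 fold change. Levels in CPM use the TMM-scaled library sizes and are given as mean ± SD over libraries. The 3 averaged comparisons set 12 libraries against 12. A comparison of 3 against 3 libraries cannot give an exact permutation p under 0.1, so gene tests rest on the pooled spread.

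Of 43 gene lists fixed beforehand, 39 with 5 or more tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and adjustment over the lists within a comparison. Of 108 list calls in the 13 comparisons, 0 held when the correlation was estimated for each list, and the rotation test fry, which asks whether a list's genes move one way on balance, called 60. Counts of members are given over all genes and adjusted over the list alone. The named genes were, for each comparison, the 12 with the largest rise and the 12 with the largest fall among called genes with a mean log2 CPM of 1 or more, no overlap between the libraries of 3 against 3, and a symbol that is not a predicted or clone name. With fewer than 10 calls all were named, with none the 4 smallest p-values, and for lists up to 4 members with the smallest p-values. Only the more informative of these are printed. Genes that passed in all 4 genotype settings, Spp1, Mstn and the atrial and adipocyte genes given by level were chosen after their values were seen.

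Correlations across libraries are given as Pearson's r and Spearman's rho with two-sided permutation tests. The replicate axis is the first principal component of the log2 CPM deviations from group means, and a library's score is its projection on it. Its sign was set so that longer transcripts lie lower at a high score, which fixes the sign of its relation to transcript length. The genes and slopes set against the score come from the same log2 CPM values as the axis. Shares of genes with the same sign compare pairs of comparisons that have no library in common.

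Before averaging, libraries were compared with each other. Of 276 pairs none were identical, and the chi-square per gene was 13.1 to 194.6, so all 24 were kept as separate samples. Replicate numbers recur in every group. Deviations of libraries with the same number had r between -0.626 and 0.651, and 10 of 21 such pairs exceeded 0.1. All 3 pairs did so in the genotype comparison alone (0.211 to 0.651). There WT sham 2 and DKO sham 3, with different numbers, had r = 0.435, so these values do not show that the numbers pair its libraries. The labels do not say what a number stands for.

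The pipeline was tested on counts simulated from these libraries' means and sizes, without the replicate axis. In the genotype comparison it found 22 of 67 genes changed 2-fold and 52 of 66 changed 4-fold, and called 3 of 13266 unchanged genes. In the averaged preconditioning comparison it found 56 of 67 and 66 of 66, with 11 unchanged genes called. A raised list of 28 genes was found in each simulated comparison and 0 of 38 other lists were called. The simulated genes were drawn independently of each other, so this does not show how the list tests behave with correlated genes.

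Alternatives were RLE size factors (whose largest shift of the median fold change of all genes was -0.0943 log2), no filter on low counts, DESeq2 1.42.0, the replicate number as a block, leaving out mitochondrial, Rn45s and globin genes, leaving out each library in turn, and only the compared groups in the fit. Added after seeing the data were the replicate axis as a covariate, removal of trends with transcript length, GC content or both by natural spline offsets per library, and fits without WT HPC 1 and 2 or without DKO sham 2 and 3, which leave 1 library in that group, assumed to vary like the other groups. Pairs of comparisons were also fitted in 12 libraries each, with the axis of those libraries as a covariate, since in the joint fit an error of the axis coefficient enters both. Up to 100 splits of the libraries were refitted for each comparison. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.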

Results

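Gene expression was measured by total RNA sequencing in whole hearts of 24-week-old mice, with 24 libraries in 8 groups of 3 hearts. Per the labels, DKO mice are deficient in the low-density lipoprotein receptor, Ldlr, and homozygous for the obese mutation of the leptin gene Lep. These changes make them a mouse model of obesity with high blood lipids. C57BL/6 mice served as wild type (WT). Mice of both genotypes received captopril, an inhibitor of angiotensin-converting enzyme, at 10 mg/kg/day or saline. Hypoxic preconditioning (HPC) consisted of 5 cycles of 6 min at 6% oxygen, separated by periods at 21% oxygen, and the other mice had a sham procedure. The question behind the design was how the preconditioning response of the heart is impaired in the metabolic syndrome and whether inhibition of the enzyme restores it. Each library held between 10436616 and 15331446 reads assigned to genes, with a median of 12079000, and reads on between 15978 and 18111 of the 38926 genes. At this depth a count of 0 allows up to 3 reads, or between 0.159 and 0.358 CPM by library on the normalised scale, and this floor covers counting error only. Below, WT sham and DKO sham name the saline groups without preconditioning.

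Ldlr (chromosome 9, 21723483 to 21749919) was read at 7.15 ± 2.46 CPM in WT and 6.53 ± 2.12 CPM in DKO hearts (SD, n = 12 libraries each), with between 34 and 174 reads per library. The difference of DKO sham from WT sham was -0.23 log2 (SE 0.33, adjusted p = 0.78). Lep (chromosome 6, 29060220 to 29073877), a hormone of fat cells, was read at 0.240 ± 0.351 CPM in WT and 1.12 ± 1.04 CPM in DKO hearts (n = 12 each), with between 0 and 46 reads per library. Its difference in sham hearts was 3.35 log2 (SE 1.56, adjusted p = 0.26). A total per gene does not show whether the reads cover the altered part of the gene, so these values neither check nor contradict the genotype labels.

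The libraries differed within groups in a way that ran through most genes. The first principal component of the deviations of each library from its group mean, called the replicate axis here, held 48.3% of the variance within groups. Across the 24 libraries its score followed the slope of expression on transcript GC content with r = 0.994 and rho = 0.979 (permutation p = 1e-05 for both, the smallest the permutations can give, and adjusted p = 1.57e-05 and 2.2e-05 over the 11 relations computed). Without the 2 libraries farthest out, r was 0.988, and within groups it was 0.991. The slope on transcript length had r = -0.841 and rho = -0.735 (permutation p = 1e-05 and 0.00013, adjusted p = 1.57e-05 and 0.000204), r = -0.702 without those 2 libraries and -0.844 within groups. Genes of the Y chromosome followed the same axis, for example the RNA helicase gene Ddx3y with r = -0.960 and rho = -0.967 (permutation p = 1e-05 for both, adjusted p = 1.57e-05 and 2.2e-05, r = -0.943 without the 2 libraries and -0.914 within groups). This was not a mix of sexes: the X-inactivation RNA Xist had at most 4 reads in any library and Ddx3y at least 70, so all 24 hearts read as male. The nuclear RNA Malat1 followed the axis with r = -0.865 and rho = -0.863 (the same p-values, r = -0.921 without the 2 libraries and -0.907 within groups). These genes and both slopes come from the values that define the axis. Their p-values therefore describe what the axis holds and are not an independent test of it. The share of reads on the mitochondrial genome lay between 20.9% and 52.5% and had r = -0.485 and rho = -0.489 with the score (permutation p = 0.0161 and 0.0163, adjusted p = 0.0196 and 0.0179, r = -0.457 without the 2 libraries). Within groups its r was -0.888. The total of gene reads had r = -0.273 and rho = -0.163 (permutation p = 0.196 and 0.446, adjusted p = 0.196 and 0.446, r = -0.0412 without them and 0.078 within groups). WT HPC 2 and WT HPC 1 lay farthest out at 119.6 and 107.4, so the group mean was 86.0 ± 48.0 (SD, n = 3) in WT HPC against 15.7 ± 47.4 in WT sham. Labels of sequencing batch or date were not among the sources used here. Library identifiers of the samples ran with the design: all WT libraries came before all DKO libraries, and among WT the preconditioned ones came first. Within the preconditioned and the other WT libraries, saline came before captopril. In DKO hearts preconditioned and other libraries were mixed in that order, and the captopril libraries stood together, with saline ones before and after. If the identifiers follow the order of preparation, which is not stated, its effect cannot be told apart from genotype. The same holds for preconditioning and captopril in WT hearts.

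Between DKO and WT sham hearts 139 genes were higher and 119 lower in DKO, 258 of 13494 tested. The gene of the protein kinase Hipk2 (chromosome 6, 38694390 to 38876165) was 8.39-fold higher, with 83.1 ± 13.6 CPM in DKO sham against 9.80 ± 4.72 in WT sham (SD, n = 3 each; log2 3.07, SE 0.38, adjusted p = 0.00047). Zbtb16 (chromosome 9, 48654297 to 48836222), a transcription factor gene induced by glucocorticoids, was 4.09-fold higher, at 46.1 ± 2.26 against 11.2 ± 3.14 CPM (log2 2.03, SE 0.31, adjusted p = 0.0025). Among the other genes with the largest rise were Nt5c1a, which makes adenosine from AMP (7.77-fold, adjusted p = 0.0045), the retinoic acid hydroxylase gene Cyp26b1 (7.59-fold, adjusted p = 0.012), the potassium channel gene Kcnk1 (6.04-fold, adjusted p = 0.0045) and the cholesterol exporter gene Abcg1 (4.36-fold, adjusted p = 0.0023). The sodium-calcium exchanger gene Slc8a1 rose 4.28-fold (log2 2.10, SE 0.38, adjusted p = 0.0085) and Ppara, the nuclear receptor that drives fatty acid oxidation genes, 4.12-fold (log2 2.04, SE 0.34, adjusted p = 0.0045). Lower in DKO were the secreted phospholipase gene Pla2g2d (5.5-fold lower, log2 -2.46, SE 0.42, adjusted p = 0.0049), the complement gene C7 (3.81-fold lower, adjusted p = 0.0082), the carboxypeptidase-like gene Cpxm2 (16.0 ± 8.09 against 59.9 ± 7.19 CPM, log2 -1.91, SE 0.32, adjusted p = 0.0049) and the opioid precursor gene Penk (3.39-fold lower, adjusted p = 0.022). The mitochondrial tRNA genes mt-Ts1 (log2 -2.77, SE 0.49, adjusted p = 0.0063) and mt-Tq (log2 -2.03) were also lower, but are short and have nuclear copies, so their reads are uncertain. For 257 of the 258 genes the 3 libraries of one group lay apart from the 3 of the other, as they did for 2661 of all genes tested, where chance alone gives 10%.

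Of the 18 glucocorticoid-responsive genes tested, 3 rose in DKO sham hearts and none fell over all genes, and 9 rose when adjusted over the list alone. They were Zbtb16, Fkbp5, a co-chaperone gene of the glucocorticoid receptor (44.0 ± 4.67 against 14.8 ± 1.46 CPM, log2 1.57, SE 0.23, adjusted p = 0.0023), and the mTOR inhibitor gene Ddit4 (log2 1.57, SE 0.38, adjusted p = 0.038). The list's median was 0.63 log2, with a camera adjusted p = 1.3e-05 and an adjusted p = 0.19 with an estimated correlation. Of 21 heat shock genes, the small heat shock protein gene Hspb1 (log2 -1.13, SE 0.26, adjusted p = 0.032) and the crystallin gene Cryab (log2 -1.0, SE 0.26, adjusted p = 0.047) fell over all genes, and 8 fell when adjusted over the list alone. The list's median was -0.42, with a camera adjusted p = 4e-05 and an adjusted p = 0.2 with an estimated correlation. Of 27 extracellular matrix genes, 2 rose over all genes and 6 when adjusted over the list alone: Loxl2, which crosslinks collagen (log2 1.91, SE 0.32, adjusted p = 0.0045), and osteopontin, Spp1, at 6.65 ± 2.00 against 0.190 ± 0.0891 CPM (adjusted p = 0.047). The list's median was 0.61, with a camera adjusted p = 7.7e-07 and an adjusted p = 0.5 with an estimated correlation. Of 20 fatty acid synthesis genes, the desaturase gene Scd2 (log2 1.38, SE 0.19, adjusted p = 0.0014) and the acyltransferase gene Gpam (log2 1.76, SE 0.43, adjusted p = 0.041) rose, and 5 rose when adjusted over the list alone. For the whole list this gave a camera adjusted p = 0.011 and an adjusted p = 0.5 with an estimated correlation. No single gene of the 31 nuclear genes of oxidative phosphorylation passed over all genes in edgeR, and 2 were lower when adjusted over the list alone. Their median was -0.45, with a camera adjusted p = 7.7e-07 and an adjusted p = 0.53 with an estimated correlation.

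Beside the genotype difference stood a trend with transcript length (rho = 0.433 across genes, which are not independent replicates), and the DKO sham hearts 2 and 3 held the liver transcript Alb at 180 and 27.9 CPM. Without both DKO sham 2 and DKO sham 3 the count was 11, with 10 higher and 1 lower, but that fit sets 1 DKO library against 3, which by itself lowers the power. It was 7 with only the 2 sham groups in the fit, 98 without the length trend, 817 without the GC trend, 406 without both trends, 622 by DESeq2 and 2098 with the replicate axis as a covariate, where 958 were higher and 1140 lower. It was 29, 61, 81, 110 and 163 without WT sham 2, DKO sham 2, DKO sham 1, WT sham 1 and DKO sham 3. With DESeq2's size factors in place of TMM it was 133 higher and 75 lower, which moved the higher share from 53.9% to 63.9%.

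**Figure D1:**
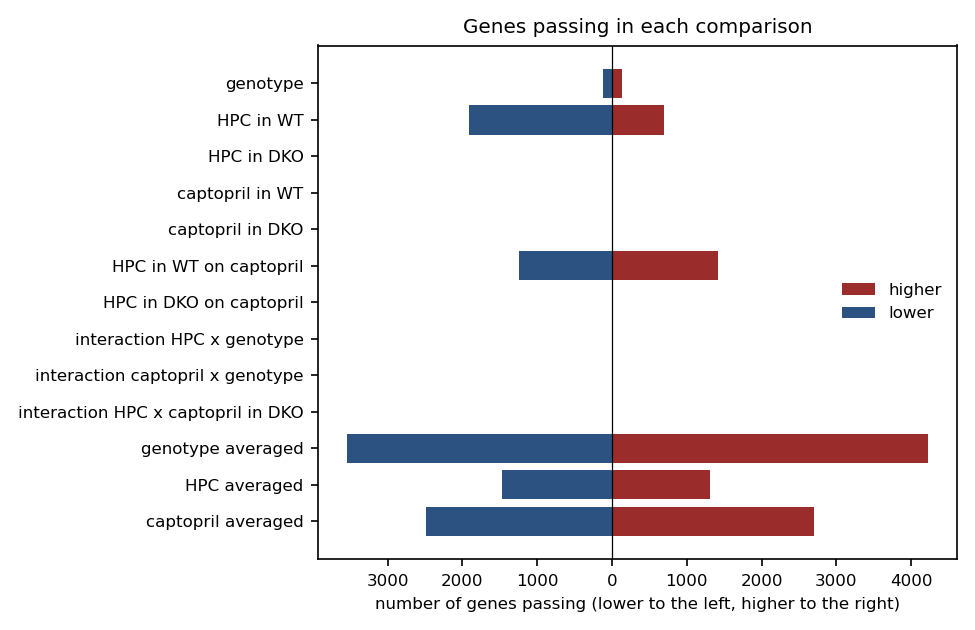
Number of genes higher and lower at an adjusted p under 0.05 in each of the 13 comparisons (edgeR, 13494 genes tested). Preconditioning has 2609 and 2659 calls in WT hearts on saline and on captopril, and the genotype 258 in sham hearts.

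The genotype difference was also computed under each treatment. It covered 7606 genes under HPC, 25 on captopril and 3667 under HPC on captopril, and 14 genes passed in all 4 settings. Under HPC the fold changes had r of size 0.707 with the replicate axis of the other libraries. Hipk2 was higher in DKO by 3.07, 3.76, 2.03 and 4.08 log2 in sham, HPC, captopril and captopril with HPC, in that order. Fkbp5 (chromosome 17, 28399094 to 28517527) was higher by 1.57, 0.85, 1.38 and 1.18, and Mstn (chromosome 1, 53061640 to 53068079), which encodes the muscle growth inhibitor myostatin, by 3.07, 4.17, 2.80 and 2.44. Mstn had 0 to 2 reads per library in WT HPC and 1 to 10 in WT sham, against 14 to 36 in DKO HPC and 19 to 54 in DKO sham. The WT reads lie near the floor of 3 reads, so the size of the Mstn differences is uncertain. The adaptor kinase gene Aak1, Kcnk1, the actin regulator gene Raph1 and Zbtb16 were higher in all 4 as well, and Cpxm2 and Sh2d4a lower. Gm5559 (chromosome 5, 95861714 to 95862715) had differences of -5.10, -5.78, -5.63 and -5.21 log2. It and Gm5652, Gm14267 and Gm5430, which also passed in all 4, are annotated as pseudogenes, so reads shared with their parent genes make them uncertain. The 12 highest and 12 lowest named genes of the sham comparison kept their sign in all 3 other settings. Of the higher ones 11, 3 and 10 passed under HPC, on captopril and under both, and of the lower ones 12, 2 and 10. Sham and captopril libraries share no heart, and 257 of the 258 genes had the same sign in both (99.6%, against 72.1% of the genes not called), with 19 called in both against 0.246 for independent lists.

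Averaged over the 4 treatment combinations, 4224 genes were higher and 3541 lower in DKO hearts. Nt5c1a was 13-fold higher (log2 3.70, SE 0.28, adjusted p = 8.4e-09, 12 libraries on each side), Hipk2 9.41-fold (log2 3.23, SE 0.19, adjusted p = 8.7e-10) and Gpam 6.78-fold (log2 2.76, SE 0.23, adjusted p = 2.9e-08). The natriuretic peptide gene Nppb was 5.74-fold lower (log2 -2.52, SE 0.24, adjusted p = 1.5e-07), skeletal actin, Acta1, 5.11-fold lower (log2 -2.35, SE 0.26, adjusted p = 6.7e-07), the adipsin gene Cfd 7.39-fold lower (adjusted p = 5.2e-06) and Cpxm2 3.85-fold lower (adjusted p = 3.1e-08). Of 21 heat shock genes 17 fell, Hspb1 (log2 -1.65, SE 0.13, adjusted p = 2.1e-08) and Cryab (log2 -1.30, SE 0.13, adjusted p = 1.9e-07) among them, and 2 rose, or 17 and 3 when adjusted over the list alone. The median of the list was -0.50, with a camera adjusted p = 0.00015 and an adjusted p = 0.74 with an estimated correlation. Of 31 oxidative phosphorylation genes 27 fell and 1 rose, over all genes and adjusted over the list alone. As a group they had a median of -0.66, with a camera adjusted p = 8.7e-09 and an adjusted p = 0.77 with an estimated correlation. Of 28 ribosomal protein genes 27 fell and none rose by both adjustments. The median over these genes was -0.69, with a camera adjusted p = 1.5e-09 and an adjusted p = 0.77 with an estimated correlation. Of 8 genes of MHC class II presentation 6 fell and 1 rose, over all genes and adjusted over the list alone. Together their median was -1.10, with a camera adjusted p = 0.029 and an adjusted p = 0.77 with an estimated correlation. The fold changes followed length with rho = 0.517 and GC content with rho = -0.433 across genes. The balance of higher and lower genes turned to 2566 and 3973 without the length trend, 3604 and 4233 without the GC trend, 2889 and 3909 without both trends, and 2964 and 3061 without both WT HPC 1 and WT HPC 2.

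With preconditioning in WT hearts 697 genes were higher and 1912 lower, 2609 in all. For 1933 of these the 3 libraries of one group lay apart from the 3 of the other, as they did for 3303 of all genes tested. Lcn2, an iron-siderophore-binding acute-phase protein gene, rose 13.3-fold, from 3.28 ± 1.10 CPM in WT sham to 43.9 ± 31.5 in WT HPC (SD, n = 3 each; log2 3.74, SE 0.50, adjusted p = 0.0034). The nicotinamide riboside kinase gene Nmrk2 rose 8.63-fold, from 3.61 ± 0.337 to 31.4 ± 22.9 CPM (log2 3.11, SE 0.60, adjusted p = 0.0081), and the metalloproteinase inhibitor gene Timp1 4.14-fold, from 3.28 ± 1.74 to 13.6 ± 5.14 CPM (log2 2.05, SE 0.38, adjusted p = 0.0075). Haptoglobin, Hp (4.35-fold, adjusted p = 0.043), the chemokine gene Ccl8 (3.96-fold, adjusted p = 0.012), angiotensinogen, Agt (3.08-fold, adjusted p = 0.012), Serpina3n (2.96-fold, adjusted p = 0.016), galectin-3, Lgals3 (2.93-fold, adjusted p = 0.028), and the interferon-induced gene Ifi27l2a (2.7-fold, adjusted p = 0.008) rose as well. The Rho GTPase-activating protein gene Arhgap5 was 13.9-fold lower (log2 -3.80, SE 0.85, adjusted p = 0.012) and Calcrl, the receptor gene for adrenomedullin, 13.3-fold lower (log2 -3.74, SE 0.86, adjusted p = 0.013). Lmbrd2 was read at 1.35 ± 0.847 CPM in WT sham and had 0 reads in the 3 WT HPC libraries, which allows up to 0.358 CPM.

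Among the gene groups, of 28 ribosomal protein genes 16 rose and none fell over all genes, and 21 rose when adjusted over the list alone (Rps6 0.79 log2, SE 0.21, adjusted p = 0.019). The list's median was 0.73, with a camera adjusted p = 8.9e-10 and an adjusted p = 0.77 with an estimated correlation. Of 31 oxidative phosphorylation genes 10 rose and 1 fell, or 16 and 3 when adjusted over the list alone, with the cytochrome oxidase genes Cox5b (log2 0.87, SE 0.23, adjusted p = 0.018) and Cox6a2 (log2 1.05, SE 0.28, adjusted p = 0.019) higher and the complex I gene Ndufs1 lower (log2 -0.79, SE 0.16, adjusted p = 0.01). The list's median was 0.51, with a camera adjusted p = 7e-05 and an adjusted p = 0.77 with an estimated correlation. Of 23 genes of insulin and IGF signalling 10 fell and none rose, and 11 fell when adjusted over the list alone, among them the receptor gene Insr (log2 -1.44, SE 0.39, adjusted p = 0.021), its substrate gene Irs1 (log2 -2.21, SE 0.56, adjusted p = 0.017) and the coactivator gene Ppargc1a (log2 -1.63, SE 0.38, adjusted p = 0.013). Their median was -0.68, with a camera adjusted p = 0.012 and an adjusted p = 0.77 with an estimated correlation. Of 5 neutrophil marker genes 3 rose, or 4 when adjusted over the list alone, with S100a8 at 2.80 log2 (SE 0.72, adjusted p = 0.017) and S100a9 at 2.41 (SE 0.75, adjusted p = 0.033). The members had a median of 1.42, with a camera adjusted p = 0.015 and an adjusted p = 0.46 with an estimated correlation. Of 24 target genes of the hypoxia-inducible factor none rose and 4 fell, or 3 when adjusted over the list alone: Adm (log2 -1.12, SE 0.34, adjusted p = 0.03), Hk2 (log2 -0.75), Pdk1 (log2 -1.0) and Kdm3a (log2 -0.75). That list did not pass as a whole (camera adjusted p = 0.57, and adjusted p = 0.77 with an estimated correlation). Of 11 atrial muscle genes the potassium channel gene Kcnj3 fell (log2 -1.56, SE 0.54, adjusted p = 0.046), and none passed when adjusted over the list alone. Their median was 0.17, their mean -0.17 and the camera direction up, with a camera adjusted p = 0.91 and an adjusted p = 0.97 with an estimated correlation.

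The genes that rose in WT HPC had a median transcript length of 1496 nt and a GC content of 54.5%, those that fell 4933 nt and 44.5%, and those not called 3274 nt and 50.6%. Across genes the fold change had rho = -0.464 with length and 0.625 with GC content, and r of size 0.723 with the replicate axis computed from the 18 libraries of the other 6 groups. With the axis as a covariate 1049 genes passed, 709 of them among the 2609, 1511 passed after the length trend was removed, 1062 of them the same, and 1519 after the length and GC trends were removed. With the axis as a covariate 168 were higher and 881 lower, without the length trend 675 and 836, without the GC trend 1015 and 1158, and without both trends 726 and 793. The count was 0 with only these 2 groups in the fit, where all named genes lost their call, 0 without both WT HPC 1 and WT HPC 2, which leaves 1 library in WT HPC, and 1, 9, 609 and 613 without WT HPC 1, WT HPC 2, WT sham 1 and WT sham 3, against 4102 and 5265 without WT sham 2 and WT HPC 3.

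In WT hearts on captopril, 1420 genes were higher and 1239 lower with preconditioning, 2659 in all. The libraries of the 2 groups lay apart for 2545 of these and for 4516 of all genes tested. Nmrk2 rose 9.9-fold (log2 3.31, SE 0.62, adjusted p = 0.0012, n = 3 each) and Lcn2 8.2-fold, from 2.07 ± 0.527 to 17.1 ± 6.11 CPM (log2 3.04, SE 0.51, adjusted p = 0.00064). Lgals3 rose 8.01-fold, from 3.57 ± 0.816 to 28.8 ± 14.4 CPM (log2 3.00, SE 0.50, adjusted p = 0.00062), and Timp1 6.64-fold, from 1.14 ± 0.317 to 7.65 ± 1.76 CPM (log2 2.73, SE 0.43, adjusted p = 0.00041). The transferrin gene Trf rose 3.94-fold (adjusted p = 0.00025) and Hp 4.44-fold (adjusted p = 0.048). Nt5c1a was 14.2-fold lower (log2 -3.83, SE 0.67, adjusted p = 0.00083), Gpam 10.8-fold lower (adjusted p = 0.00018) and the vinculin gene Vcl, which anchors actin at cell contacts, 10.4-fold lower (log2 -3.37, SE 0.41, adjusted p = 6.9e-05). The phosphodiesterase gene Pde3a was 9.76-fold lower (adjusted p = 6e-04), Ppara 8.96-fold lower (log2 -3.16, SE 0.38, adjusted p = 6.9e-05) and Slc8a1 8.2-fold lower (adjusted p = 0.00014). Of 28 ribosomal protein genes 25 rose and none fell, and 28 rose when adjusted over the list alone (Rps20 1.62 log2, SE 0.24, adjusted p = 0.00028). The median of the list was 1.09, with a camera adjusted p = 3.1e-14 and an adjusted p = 0.95 with an estimated correlation. Of 31 oxidative phosphorylation genes 13 rose and 2 fell, or 19 and 3 when adjusted over the list alone (Cox5b 1.23 log2, SE 0.23, adjusted p = 0.0012). The list had a camera adjusted p = 0.00011 and an adjusted p = 0.95 with an estimated correlation. Of 23 insulin and IGF signalling genes 6 fell, or 10 when adjusted over the list alone, with Irs1 at -2.36 log2 (SE 0.52, adjusted p = 0.0035) and Irs2 at -2.85 (SE 0.76, adjusted p = 0.012). As a list they had a camera adjusted p = 0.0066 and an adjusted p = 0.95 with an estimated correlation. None of the 24 hypoxia-inducible factor targets passed in edgeR. Of 11 atrial muscle genes 1 rose, over all genes and adjusted over the list alone, the lipid transfer gene Stard10 (log2 1.96, SE 0.58, adjusted p = 0.022). Over the atrial list the median was 1.57, with a camera adjusted p = 0.22 and an adjusted p = 0.95 with an estimated correlation. The atrial genes Myl7 (88.8 ± 96.1 to 682 ± 510 CPM, adjusted p = 0.066), Nppa (64.4 ± 64.3 to 384 ± 256, adjusted p = 0.096) and Sln (22.5 ± 22.9 to 174 ± 129, adjusted p = 0.067) had higher means in the preconditioned group and did not pass.

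In this comparison the genes that rose had a median length of 1646 nt, those that fell 4916 nt and those not called 3480 nt, with rho = -0.493 for length, 0.305 for GC content and r of size 0.238 for the replicate axis of the other libraries. The count was 729 with only these 2 groups in the fit, 1366 after the length trend was removed and 4760 with the axis as a covariate, and it was 1306 and 1437 without WT captopril HPC 2 and WT captopril 2. Lower genes outnumbered higher ones with DESeq2's size factors (1368 against 1244), by DESeq2 (1564 against 1362), without the filter on low counts (1291 against 865), and without the length trend (745 against 621), the GC trend (1814 against 1616) or both (1241 against 1049).

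**Figure D2:**
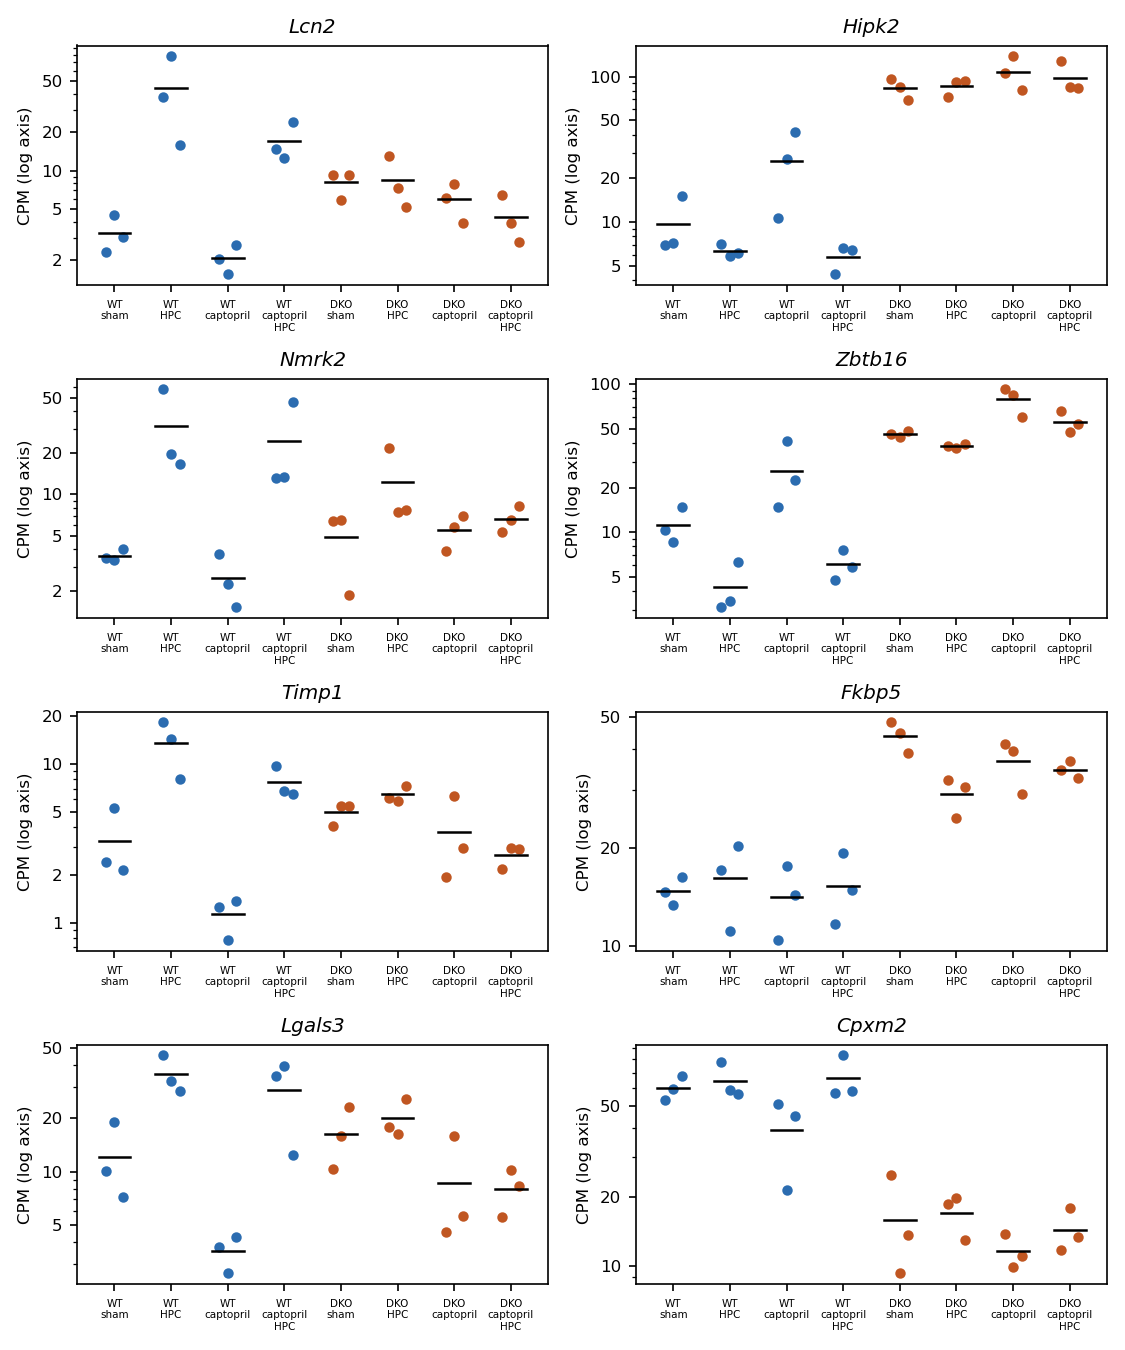
CPM of 8 genes in each library, by group, on a log axis, with a black bar at the group mean, blue for WT and orange for DKO. Lcn2, Nmrk2, Timp1 and Lgals3 are higher in the preconditioned WT groups (Lcn2 43.9 against 3.28 CPM on saline and 17.1 against 2.07 on captopril), Hipk2, Zbtb16 and Fkbp5 are higher in DKO sham and Cpxm2 is lower (16.0 against 59.9).

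The responses of WT hearts on saline and on captopril share no library. Of the 2609 genes changed on saline, 96.4% had the same sign on captopril, against 72.2% of the genes not called, and 1161 passed in both in the same direction, against 249 for independent lists. The fold changes had r = 0.61 across all genes tested, which are not independent replicates. With the replicate axis as a covariate, each response fitted in its own 12 libraries so that no coefficient was shared, r was 0.593. In these fits 351 and 4977 genes passed, 234 of them in both in the same direction, against 63.7 for independent lists. Of the 12 named genes that rose on saline, 12 had the same sign on captopril and 10 passed there, and of the 12 that fell on saline, 10 had the same sign and 3 passed. Of the 12 named genes that rose on captopril, 11 had the same sign on saline and 8 passed, and of the 12 that fell on captopril, 12 and 11. Lcn2, Nmrk2, Timp1, Lgals3 and Hp rose in both.

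In DKO hearts no gene passed for preconditioning, by edgeR, with 293 genes at an unadjusted p under 0.05 and 2 calls by DESeq2. Lcn2 was at 8.18 ± 1.95 CPM in DKO sham and 8.47 ± 3.98 in DKO HPC, and Nmrk2 at 4.92 ± 2.65 and 12.3 ± 8.20 (SD, n = 3 each). The smallest p-values belonged to transthyretin, Ttr (log2 -5.25, SE 0.90, adjusted p = 0.12), the apolipoprotein gene Apoa2 (log2 -4.74, SE 0.91, adjusted p = 0.26), Pydc3 (log2 1.38, SE 0.29, adjusted p = 0.43) and Map3k6 (log2 -0.78, SE 0.18, adjusted p = 0.92). Ttr and Apoa2 are liver transcripts, read at 16.5 and 17.7 CPM in DKO sham 2 and at 3.07 and 3.66 in DKO sham 3. None of 18 glucocorticoid-responsive genes passed over all genes and 2 were lower when adjusted over the list alone, the clock gene Per1 (log2 -1.09, SE 0.31, adjusted p = 0.92 over all genes) and Errfi1 (log2 -0.94). Over the whole list the median was -0.43, with a camera adjusted p = 2.6e-07 and an adjusted p = 0.13 with an estimated correlation. None of 23 glycolysis genes passed. As a group they had a median of -0.34, with a camera adjusted p = 2.6e-07 and an adjusted p = 0.51 with an estimated correlation. The count was 11 without DKO sham 1, 14 without the filter on low counts and 1 without the length and GC trends. With only the 2 compared groups in the fit it was 0, as it was for preconditioning in WT hearts on saline.

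In DKO hearts on captopril no gene passed for preconditioning by edgeR, with 226 at an unadjusted p under 0.05 and 0 calls by DESeq2. The smallest p-values were those of Pdzd4 (log2 0.95, SE 0.26), the LIM protein gene Pdlim2 (log2 0.68, SE 0.20), Tm4sf1 (log2 0.63, SE 0.19) and 2410006H16Rik (log2 0.83, SE 0.26), all at an adjusted p of 1. None of 28 ribosomal protein genes passed singly. The median over these genes was 0.46, with a camera adjusted p = 1.2e-20 and an adjusted p = 0.56 with an estimated correlation. Of the 2609 genes changed by preconditioning in WT hearts, 27.7% had the same sign in DKO hearts and 76.7% in DKO hearts on captopril, against 34.5% and 56.9% of the genes not called. The fold changes of preconditioning followed the replicate axis of the other libraries with r of size 0.628 in DKO and 0.205 in DKO on captopril. Across genes their rho with GC content was 0.625 in WT, -0.568 in DKO and 0.0921 in DKO on captopril. With preconditioning the mean axis score went from 15.7 to 86.0 in WT hearts and from 6.56 to -18.5 in DKO hearts. The 27.7% can therefore not be told apart from opposite places of the libraries on the axis. With the axis as a covariate the share in DKO was 71.2% of the 1049 genes then called. That fit shares the axis coefficient between both responses. In separate fits of WT and DKO libraries it was 63.2% of 19 genes called, against 60.4% of those not called. The genes called in WT were drawn anew in each fit. The share was 51.1% of 609 genes without WT sham 1, and 16.7% of 2576 and 17.1% of 2615 without DKO sham 1 and DKO HPC 1. Without WT HPC 1 only 1 gene was called and without WT HPC 2 only 9, too few for a share.

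The difference of the preconditioning response between DKO and WT passed for 6 genes, 5 higher and 1 lower in DKO than in WT. Lcn2 had a difference of -3.69 log2 (SE 0.66), the SUMO protease gene Senp5 2.71 (SE 0.46), the microtubule protein gene Eml4 1.86 (SE 0.33), the centromere gene Cenpc1 2.75 (SE 0.49) and the histone chaperone gene Supt16 2.26 (SE 0.40), each at an adjusted p of 0.044, and the autophagy protease gene Atg4c 2.32 (SE 0.43, adjusted p = 0.05 when rounded). At an unadjusted p under 0.05 there were 4199 genes, and DESeq2 called 1512. In data simulated from these libraries, this comparison found 2 of 67 genes changed 2-fold and 37 of 66 changed 4-fold. The oxidative phosphorylation genes had a median of -0.75 (camera adjusted p = 1.1e-05, and adjusted p = 0.69 with an estimated correlation) and the ribosomal protein genes -0.67, with a camera adjusted p = 1.1e-05 and an adjusted p = 0.69 with an estimated correlation. The fold changes had rho = -0.695 with GC content and r of size 0.79 with the replicate axis of the other libraries. No gene passed with the replicate number as a block, with the axis as a covariate, without the length trend, with only these 4 groups in the fit, or without both WT HPC 1 and WT HPC 2 or both DKO sham 2 and DKO sham 3. The count was 71 without the GC trend, 38 without both trends and 980 without the filter on low counts. It was also 0 without any one of WT sham 1 and 3, WT HPC 1 and 2, DKO sham 2 and 3, and DKO HPC 2 and 3, whereas 104, 951, 2298 and 4242 passed without DKO HPC 1, DKO sham 1, WT sham 2 and WT HPC 3.

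Whether captopril altered the preconditioning response of DKO hearts was tested as a difference of differences, and no gene passed by edgeR, with 152 at an unadjusted p under 0.05 and 0 calls by DESeq2. The smallest p-values were those of Gm16153 (log2 -4.88, SE 1.29), Spp1 (log2 -4.82, SE 1.29), Hils1 (log2 -3.43, SE 0.90) and Cyp2f2 (log2 5.82, SE 1.60), at an adjusted p of 0.99.

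No gene passed for captopril in WT sham hearts by edgeR, with 1940 at an unadjusted p under 0.05 and 2 calls by DESeq2. The smallest p-values were those of the water channel gene Aqp8 (log2 -1.69, SE 0.32), the exportin gene Xpo4 (log2 1.41, SE 0.29), the peptidase inhibitor gene Pi16 (log2 -0.99, SE 0.21) and Arel1 (log2 0.72, SE 0.16), all at an adjusted p of 0.32. None of 27 extracellular matrix genes passed over all genes and 9 were lower when adjusted over the list alone, with collagen I, Col1a1, at 40.8 ± 26.0 CPM against 91.3 ± 46.6 in WT sham (log2 -1.16, SE 0.38, adjusted p = 0.32). Together their median was -0.68, with a camera adjusted p = 4.5e-06 and an adjusted p = 0.57 with an estimated correlation. None of 11 atrial muscle genes passed. Their median was -1.89, with a camera adjusted p = 0.0023 and an adjusted p = 0.57 with an estimated correlation. The atrial light chain gene Myl7 was read at 88.8 ± 96.1 CPM on captopril and 475 ± 277 in WT sham. The fold changes had rho = -0.594 with GC content and r of size 0.622 with the replicate axis of the other libraries. The count was 3 without WT sham 3, 1 with the axis as a covariate, 1 without the GC trend and 2 without the length and GC trends.

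In DKO sham hearts no gene passed for captopril by edgeR either, with 1732 at an unadjusted p under 0.05 and 8 calls by DESeq2. The 3 libraries of one group still lay apart from the 3 of the other for 4108 of all genes tested, where chance alone gives 10%. For genotype in sham hearts they did so for 2661. The smallest p-values were those of Ttr (log2 -4.93, SE 0.87, adjusted p = 0.16), the carboxylesterase gene Ces2e (log2 -2.11, SE 0.41), Hils1 (log2 3.60, SE 0.68), both at an adjusted p of 0.27, and Apoa2 (log2 -4.08, SE 0.85, adjusted p = 0.34), which was 0.05 log2 in the fit without DKO sham 2 and 3. None of 27 extracellular matrix genes passed over all genes and 13 were lower when adjusted over the list alone, with Col1a1 at 61.3 ± 13.3 CPM against 143 ± 34.1 and the basement membrane collagen gene Col4a1 at -1.34 log2 (SE 0.32, adjusted p = 0.34). For the list the median was -0.71, with a camera adjusted p = 1.9e-10 and an adjusted p = 0.41 with an estimated correlation. None of 8 genes of MHC class II presentation passed over all genes and 6 were lower when adjusted over the list alone, with H2-Ab1 at -1.57 log2 (SE 0.41, adjusted p = 0.34). The members had a median of -1.42, with a camera adjusted p = 0.00048 and an adjusted p = 0.41 with an estimated correlation. The fold changes had rho = -0.591 with GC content and r of size 0.741 with the replicate axis of the other libraries, and the count was 20 without DKO sham 1 and 47 without the filter on low counts. For a difference of the captopril response between DKO and WT no gene passed by edgeR, with 254 at an unadjusted p under 0.05 and 0 calls by DESeq2. Its smallest p-values were those of the volume-regulated channel gene Lrrc8e (log2 -2.62, SE 0.60), H2-Ob (log2 -2.34, SE 0.58), the glycogen phosphorylase gene Pygl (log2 -1.07, SE 0.27) and Pthlh (log2 -1.80, SE 0.48), at an adjusted p of 1.

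Averaged over the 4 combinations of genotype and preconditioning, captopril was associated with 2705 higher and 2483 lower genes. Of the 4 combinations on their own, WT hearts under HPC had calls by edgeR, 1394 higher and 503 lower, with r of size 0.839 between the fold changes and the replicate axis of the other libraries. The other 3 had none by edgeR, with 1940, 1732 and 346 genes at an unadjusted p under 0.05 in WT sham, DKO sham and DKO hearts under HPC, and 2 and 8 calls by DESeq2 in the sham hearts. Acta1 was 3.01-fold lower (log2 -1.59, SE 0.26, adjusted p = 0.0063, 12 libraries on each side), the apolipoprotein gene Apod 2.52-fold lower (adjusted p = 0.011) and Col1a1 2.31-fold lower (log2 -1.21, SE 0.19, adjusted p = 0.0063). The clock repressor gene Nr1d1 was 2.23-fold lower (adjusted p = 0.014), Serpina3n 2.14-fold lower (adjusted p = 0.0069) and Lgals3 2.1-fold lower (log2 -1.07, SE 0.23, adjusted p = 0.011). Higher were Malat1 (log2 1.62, SE 0.60, adjusted p = 0.04) and the p53 inhibitor gene Mdm4 (log2 1.56, SE 0.39, adjusted p = 0.014). Of 27 extracellular matrix genes 20 fell and none rose over all genes, and 21 fell when adjusted over the list alone, among them Col4a1 (log2 -1.01, SE 0.16, adjusted p = 0.0063). The median of the list was -0.70, with a camera adjusted p = 5.5e-09 and an adjusted p = 0.65 with an estimated correlation. Of 8 genes of MHC class II presentation 7 fell over all genes and adjusted over the list alone, with H2-Ab1 at -0.90 log2 (SE 0.20, adjusted p = 0.011). As a group they had a median of -0.71, with a camera adjusted p = 0.012 and an adjusted p = 0.65 with an estimated correlation. Of 23 glycolysis genes 15 fell and 1 rose, or 18 and 1 when adjusted over the list alone. The median over these genes was -0.36, with a camera adjusted p = 0.0011 and an adjusted p = 0.65 with an estimated correlation. Of 16 macrophage markers 10 fell and 1 rose, over all genes and adjusted over the list alone, with the complement gene C1qb at -0.67 log2 (SE 0.14, adjusted p = 0.0096). Together their median was -0.51, with a camera adjusted p = 0.02 and an adjusted p = 0.65 with an estimated correlation. Of 14 renin-angiotensin and kinin genes 3 rose and 4 fell by both adjustments, with Agt at -0.94 log2 (SE 0.18, adjusted p = 0.0089) and the gene of the drug's target enzyme, Ace, at -0.69 (SE 0.14, adjusted p = 0.0097), while the list as a whole did not pass (median 0.06, camera direction down, camera adjusted p = 0.88, and adjusted p = 0.92 with an estimated correlation).

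The averaged captopril fold changes had rho = -0.688 with GC content. With the replicate axis as a covariate 1 gene passed and all genes named here lost their call, with Malat1 at -0.1 log2. The count was 2831 without the GC trend, with 1335 higher and 1496 lower, and 2781 without the length and GC trends, with 1323 and 1458, and without the length trend 2244 were higher and 2802 lower. It was 0 without both WT HPC 1 and WT HPC 2 and 4 without both DKO sham 2 and DKO sham 3, and 2858, 2888, 2899, 2917 and 3458 without WT HPC 2, WT captopril 2, WT sham 2, WT captopril HPC 3 and WT HPC 1.

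Averaged over genotype and captopril, preconditioning was associated with 1316 higher and 1473 lower genes. In DKO hearts alone it had 0 calls by edgeR, on saline and on captopril. Nmrk2 rose 4.02-fold (log2 2.01, SE 0.29, adjusted p = 0.00049, 12 libraries on each side), Lcn2 3-fold (log2 1.59, SE 0.24, adjusted p = 0.00061), Lgals3 2.27-fold (log2 1.18, SE 0.23, adjusted p = 0.0022) and Timp1 2.25-fold (log2 1.17, SE 0.19, adjusted p = 0.001). In DKO hearts on captopril, where none of them passed, the means without and with HPC were 5.97 and 4.36 CPM for Lcn2, 8.67 and 8.01 for Lgals3, 3.72 and 2.69 for Timp1 and 5.55 and 6.68 for Nmrk2. The HPC response of Lcn2 had a genotype difference of -3.69 log2 (adjusted p = 0.044), a call lost with the replicate block and with the axis as a covariate. Lower were the palladin gene Palld (2.87-fold lower, log2 -1.52, SE 0.19, adjusted p = 0.00037), Vcl (2.85-fold lower, log2 -1.51, SE 0.19, adjusted p = 0.00037) and Irs2 (2.75-fold lower, adjusted p = 0.0059). Of 28 ribosomal protein genes 27 rose and none fell, over all genes and adjusted over the list alone (Rpl11 0.76 log2, SE 0.12, adjusted p = 0.00083). Over these genes the median was 0.60, with a camera adjusted p = 3.7e-18 and an adjusted p = 0.79 with an estimated correlation. Of 23 insulin and IGF signalling genes 10 fell over all genes and 12 when adjusted over the list alone, with Irs1 at -1.08 log2 (SE 0.24, adjusted p = 0.0046). The members had a median of -0.29, with a camera adjusted p = 0.0016 and an adjusted p = 0.79 with an estimated correlation. The fold changes had rho = -0.541 with length and 0.391 with GC content. The count was 1239 after the length trend was removed, 989 without both WT HPC 1 and WT HPC 2, and 4555 with the axis as a covariate.

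Whether the captopril fold changes of DKO hearts ran against the genotype difference was read from pairs of comparisons without a common library. No gene passed for captopril in DKO sham hearts (edgeR, 1732 at an unadjusted p under 0.05, 8 calls by DESeq2) or in DKO hearts under HPC (edgeR, 346 at an unadjusted p under 0.05), so these shares count signs and not changed genes. Of the 7606 genes that differed between DKO and WT under HPC, 17.3% had the opposite sign for captopril in DKO sham hearts, against 36% of the genes not called. Both sets of fold changes followed the replicate axis of the other libraries, with r of size 0.707 and 0.741. With the axis as a covariate the share was 54.8% of the 3268 genes then called, in a fit that shares the axis coefficient between both comparisons. With separate fits of the preconditioned and the other libraries it was 20.9% of 325 genes, against 44.9% of those not called. In the second pair, of the 258 genes that differed between DKO and WT sham hearts, 48.8% had the opposite sign for captopril in DKO hearts under HPC, against 50.3% of the genes not called.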

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

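The tests of GC content and of both explanations for the liver transcripts, and the replicate axis as a covariate, jointly or in separate fits, were chosen only after the results they bear on were seen.

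The response to preconditioning differed between DKO and WT hearts for 6 genes by the interaction test. The differences, DKO minus WT, were 2.32 log2 for Atg4c, 2.75 for Cenpc1, 1.86 for Eml4, -3.69 for Lcn2, 2.71 for Senp5 and 2.26 for Supt16. Of 100 splits of these libraries 9 called 6 genes or more, the highest of the others 6007, so chance cannot be excluded, and a split that calls so many times the real count points to a structure of the samples. None of the 6 passed with the replicate number as a block.

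For the preconditioning response of WT hearts, the first pattern, mitochondrial transcripts taking a varying share of the counts were tested by leaving those genes out. Of the 2609 calls 98.2% remained, over the bound of 50% set against that explanation. But TMM trims extreme genes before scaling in either fit, so the test could hardly change the calls and decides little. The mitochondrial share itself had r = -0.888 with the replicate axis within groups. GC content and transcript length stay open: rho was 0.625 and -0.464, and 53.1% and 40.7% of the calls were still made in the same direction after removal of each trend, but 897 of the 2609 after removal of both and 709 with the axis, which has r = 0.994 with the GC slope, as a covariate. The bound set beforehand against length, 50% of the calls left, is met by the count of all calls (57.9%) and not by that of the same calls, used because a count does not say which genes remain. The bound written against GC content, 50% of the same calls, is met by the 53.1%. It was not read as excluding GC content, because under 50% remained without both trends and with the axis. That further condition was not part of the bound as written. An axis that also separates replicates of one group is consistent with the values, since the response had r of size 0.723 across genes with the axis of the other 18 libraries. Preconditioning itself, beyond that axis, may contribute as well. The responses on saline and on captopril, each fitted in its own 12 libraries with their axis as a covariate, had r = 0.593. That r does not single out preconditioning, since 73.7% of the genes not called shared their sign too. Both responses had length trends (rho -0.464 and -0.493 without the covariate), which these fits did not remove separately. In both, the preconditioned libraries also came first by library identifier. The part that each explanation contributes cannot be read from 3 hearts per group.

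The second pattern is a set of liver transcripts in DKO sham hearts. Alb was read at 180 and 27.9 CPM in DKO sham 2 and 3, with 2193 and 526 reads, at 0 in DKO sham 1 and with at most 1 read elsewhere. A lowering of liver transcripts by captopril or preconditioning in DKO hearts stays open: DKO sham 1 lay above all 9 treated DKO libraries for 2 of the 9 markers detected, but a single library decides nothing. Liver RNA carried over into single hearts cannot be told apart from other sources here: 8 of the 9 markers lay within 4-fold of the median ratio of DKO sham 2 to DKO sham 3, which was 5.35, and the exception Hp, at a ratio of 1.26, was read at up to 23.5 CPM in other hearts, which hides a small share.

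The third pattern is the place of genotype differences near the 2 engineered loci. Of the 254 called genes with coordinates, 6 lay within 10 Mb of Ldlr or Lep, against 190 of 13372 tested, an odds ratio of 1.7 (95% interval 0.61 to 3.83, Fisher's exact test, two-sided, p = 0.18). They were Amotl1, Sesn3 and Ubl5 near Ldlr, and Arf5, Klhdc10 and Hipk2 near Lep, the last at 9.62 Mb and higher in DKO in all 4 settings. Chromosome segments carried with the alleles may contribute, but the interval includes both 1 and values above 2, so that explanation and an effect of the genotype itself cannot be told apart with 6 genes.

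For the other comparisons the same libraries were split in other ways. With 3 against 3 hearts there are 10 splits, so a share under 0.05 is not possible. For genotype 1 of 10 splits, the real one, called as many as 258, and the highest other called 14. The 3 other splits that part all 3 replicate numbers, as the real one does, called 0, and the 14 came from the 6 that part 1 number. For preconditioning in WT 2 of 10 called as many as 2609, the other 4995, and on captopril 1 of 10 called as many as 2659 and the highest other 0. For captopril in WT, 10 of 10 reached the real count of 0, and another split called 4918, which points to a structure of the samples. For preconditioning in DKO, captopril in DKO and preconditioning in DKO on captopril, 10 of 10 splits reached the real count of 0 and the highest other was 0. Over 100 splits, 1 reached 7765 for genotype averaged (highest other 6199) and 1 reached 2789 for preconditioning averaged (highest other 1632), the real split in each case. These shares under 0.05 go against chance assignment alone. They do not say what sets the real split apart, since library identifiers also ran with genotype and, in WT hearts, with preconditioning. Splits that call so many still point to a structure of the samples, and preconditioning averaged had 989 calls without WT HPC 1 and 2. For captopril averaged 2 reached 5188, which is also a share under 0.05. But the other one, a split of the same libraries that is not the captopril split, called 7839, which points to a structure of the samples, and 1 gene passed with the axis as a covariate and 0 without WT HPC 1 and 2, so the count is not shown to come from captopril. For the 2 other interactions, 100 of 100 splits reached the real count of 0, with a highest other of 3266 for captopril by genotype and 0 for preconditioning by captopril in DKO.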

How the results depend on the processing

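The fits with the replicate axis as a covariate, jointly or in separate fits, without length or GC trends, and without pairs of libraries were chosen after seeing the data; where a value below differs from the report, the cause was not tested unless the alternative uses fewer libraries. Only the counts of genes that moved by over 1.5 times are given, in the order of the settings. With the axis as a covariate, 2098 genes were called for genotype, 1049 for preconditioning in WT, 1 for captopril in WT, 4760 for preconditioning in WT on captopril, 0 for the preconditioning by genotype interaction, 4555 for preconditioning averaged and 1 for captopril averaged; Malat1 in captopril averaged was -0.1 log2, and the oxidative phosphorylation genes turned direction, with a camera adjusted p of 0.67 for captopril in DKO and 0.39 for captopril averaged. Without the length trend the counts were 98 for genotype, 1511 for preconditioning in WT, 1366 on captopril, 0 for that interaction and 1239 for preconditioning averaged. Without the GC trend they were 817 for genotype, 1 for captopril in WT, 71 for the interaction and 2831 for captopril averaged, and without both trends 406, 2, 38 and 2781, with 1519 for preconditioning in WT and 1 in DKO. Without DKO sham 2 and 3, which leaves 1 library in that group, they were 11 for genotype, 0 for the interaction and 4 for captopril averaged, with Apoa2 in captopril in DKO at 0.05 log2. Without WT HPC 1 and 2, which also leaves 1, they were 0 for preconditioning in WT, 0 for the interaction, 989 for preconditioning averaged and 0 for captopril averaged. DESeq2 called 622 for genotype, 2 for preconditioning in DKO, 2 for captopril in WT, 8 for captopril in DKO and 1512 for the interaction. With only the compared groups in the fit the counts were 7 for genotype, 0 for preconditioning in WT, 729 on captopril and 0 for the interaction. Without the filter on low counts they were 14 for preconditioning in DKO, 47 for captopril in DKO and 980 for the interaction. With the replicate block the interaction had 0 calls, and no other count of genes moved by over 1.5 times; in the gene lists it ended the calls of heat shock (adjusted p = 0.057) and interferon response (0.053) for captopril in DKO, and for single genes those of the 6 interaction genes and of Cfd in captopril averaged (0.058). RLE size factors and leaving out mitochondrial, Rn45s and globin genes moved no count of genes by over 1.5 times. Of the 108 list calls, 0 held with an estimated correlation, and fry called 60, 26 of them among the 108. Of the 7606 genes with a genotype difference under HPC, 17.3% had the opposite sign for captopril in DKO, where no gene passed by edgeR (1732 at an unadjusted p under 0.05, 8 by DESeq2), against 36% of the genes not called. The share was 54.8% of 3268 genes with the axis as a covariate, 20.9% of 325 with it in separate fits and 48.8% of 258 in the second pair. The share of WT preconditioning genes with the same sign in DKO, 27.7% of 2609, was 71.2% of 1049 with the axis and 63.2% of 19 with it in separate fits.

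Leaving out each library in turn gave 29 to 340 genes for genotype, 1 to 5265 for preconditioning in WT, 0 to 11 in DKO, 1306 to 2946 in WT on captopril and 0 to 0 in DKO on captopril, 0 to 3 for captopril in WT and 0 to 20 in DKO, 0 to 4242 for the preconditioning by genotype interaction, 0 to 0 for both other interactions, 7199 to 8440 for genotype averaged, 1990 to 4127 for preconditioning averaged and 2858 to 7117 for captopril averaged. The share with a sign opposite to the genotype difference was 15.1% to 20.9%. The share with the same sign in DKO was 16.7% to 100%, where the 100% is 1 gene, the only one called without WT HPC 1, and 9 genes were called without WT HPC 2. Depth limits genes near 3 reads per library, or 0.159 to 0.358 CPM.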

Other observations

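The test of the glucocorticoid-responsive genes over the treatment settings was chosen only after the sham result was seen.

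The atrial light chain gene Myl7 was read at 475 ± 277 CPM in WT sham, 1030 ± 24.5 in WT HPC, 88.8 ± 96.1 in WT captopril, 682 ± 510 in WT captopril HPC and 345 ± 247 in DKO sham (SD, n = 3 each). Atrial natriuretic peptide, Nppa, was at 401 ± 233, 622 ± 35.0, 64.4 ± 64.3 and 384 ± 256 CPM in the 4 WT groups in that order, and sarcolipin, Sln, a regulator of the calcium pump in atria, at 121 ± 64.8, 214 ± 35.1, 22.5 ± 22.9 and 174 ± 129. Of fat cell genes, the uncoupling protein gene Ucp1 of brown fat was at 6.96 ± 6.30 CPM in WT HPC and 0.461 ± 0.545 in WT sham, and adiponectin, Adipoq, at 6.03 ± 4.44 and 1.03 ± 0.495. Mean Adipoq was also higher with HPC in WT captopril (3.70 ± 4.05 against 1.35 ± 0.812), DKO (3.32 ± 2.56 against 1.45 ± 0.852) and DKO captopril (2.75 ± 2.09 against 1.14 ± 0.290). Mean Ucp1 was 3.79 against 1.46, 5.31 against 3.38 and 2.81 against 1.56 CPM there, in that order. The labels describe whole hearts and give no dissection by chamber.

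Of 20 clock genes 6 were higher and 4 lower with captopril averaged over the groups by edgeR, over all genes and adjusted over the list alone, while the list as a whole did not pass (camera adjusted p = 0.69, and adjusted p = 0.82 with an estimated correlation). With preconditioning in WT hearts 5 of the 20 were lower and none higher, over all genes and adjusted over the list alone (camera adjusted p = 0.36, and adjusted p = 0.77 with an estimated correlation). The time of day at which hearts were taken was not among the labels.

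A raised glucocorticoid response in DKO hearts is a hypothesis from the sham comparison, where 16 of the 18 tested members lay higher in DKO. If it held in each setting, members of the list would lie mostly higher there as well. At least 12 of 18 did so in 2 of the 3 other settings, with 15 on captopril and 14 under preconditioning on captopril, and 9 under preconditioning alone, where the median was 0.05 log2 against 0.63 in sham, and 6 members were called higher and 3 lower. The genotype difference under preconditioning had r of size 0.707 with the replicate axis, and with the axis as a covariate 11 members lay higher there, with a median of 0.41 against 0.67 in sham. The bounds set for the test were 3 settings for it and 1 or fewer against it, so the result leaves it open, and blood corticosterone or stress at handling may differ between the genotypes without a measurement here.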
